A study of Drosophila melanogaster with 4 samples.

How the data were processed

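The samples were 2 libraries immunoprecipitated with anti-GFP and 2 input libraries from L3 brains of an ato:GFP knock-in line kept at 25 °C. Per the labels' protocols, 400 brains were dissected, fixed and sonicated, 10% of the volume was kept as input, and the rest was precipitated. Replicates 1 and 2 of each kind are separate samples in the labels, which do not say whether they came from separate dissections. Reads were aligned with Bowtie2 2.2.1, per the submitters' processing notes. The peak caller, its threshold, the use of the input libraries as control, the genome build, any filter on reads that align at several places, and whether replicates were pooled before calling are not given in the sources used here. This bears on the results, because peaks in repeated sequence depend on how such reads are placed.

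The authors deposited 1 list of peaks for the whole series, without a header, with the sequence, start, end, name and a whole-number score of each peak. The scale of the deposited score is not given. Its lowest value, 13, is what 10 times −log10 of 0.05 gives when rounded down, but no source says that the score is on that scale. It was used only within this list, to rank and filter peaks and to compare groups of its peaks. The size of a difference in mean score and the value of Pearson's r depend on that unknown scale, whereas medians, score classes and Spearman's rho use the order of the scores alone. Peak names run from 1 to 3280 without a gap. The list has no column for a single library, so no spread between replicates, no fold over input and no depth can be given. Intervals and p-values below cover peaks or windows of this list and not biological replicates.

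The sequence names ending in Het belong to release 5 of the fly genome, whereas the gene table at hand is of release 6. Coordinates were not converted between them. For that reason 9 analyses planned before the data were examined were not run. They concerned promoter and intron shares, E-box and hexamer content of peaks, fixed gene lists, and non-coding and repeated genes near peaks. The plan was to name ato, the 15 peaks with the highest score and members of the gene lists, and of these the 15 peaks could be given, by position. The text names the runs of 12 or more peaks and the window of 100 kb with most peaks, a choice made after the data were seen. The planned results that could be computed were the number and width of peaks and their density per arm. For the density, an exact binomial test against the share of the length of the main arms was planned, and it is not given here in that form. The inclusion of the Het sequences in that test, with length taken from the last peak, was not in the plan. Nor was the comparison of Het with arm sequences. The comparisons of score, position along arms, X against autosomes and clustering were added after the list had been seen.

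Starts were converted to positions counted from 1. The length of a sequence was taken as the end of its last peak. Density on the 6 Het sequences was compared with that on the 6 arms by an exact permutation test of mean peaks per Mb over the 924 ways of choosing 6 of 12 sequences, and its ratio was given a 95% interval from 10000 bootstrap draws of complete windows of 100 kb (89 on Het sequences, 1194 on arms). Single sequences and the 2 Mb nearest the centromere of each long arm were tested by exact binomial tests with Benjamini-Hochberg adjustment at 0.05. The centromere was taken to lie at the high end of the coordinates of 2L, 3L and X and at the low end of 2R and 3R. Means of scores, and counts per complete 1 Mb bin, were compared by permutation tests with 100000 resamples. For the counts, the 2 complete bins nearest the centromere and the incomplete last bin of each arm were left out. On 2L, 3L and X the incomplete bin lies at the centromere end, so more than 2 Mb was left out there. The Het share was given in 4 classes of score, and the highest and lowest classes were compared by Fisher's exact test, with Wilson intervals that cover counting error only. Peaks less than 1 kb apart were called close, and their share was compared with 1000 random placements on the same sequence or within the same window of 100 kb. The classes were split at scores of 18, 25 and 36, so tied scores stay together. A stricter list was made of the peaks with scores above 25, the median.

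The tests were checked on 100 simulated lists of 3280 peaks for the comparison of Het with arm sequences. With a planted ratio of 4 the mean recovered ratio was 3.99, and 100 lists passed the threshold. With none planted the mean ratio was 1, and 4 of 100 lists passed. For the comparison along arms, 1 of 20 lists without an effect gave a call on some arm. The simulated peaks were placed independently of each other. These rates therefore do not cover clustered peaks such as those of the real list. Alternatives covered a stricter score, the ends of sequences, merged peaks, runs, left-out sequences and other distances. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.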

Results

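Chromatin immunoprecipitation followed by sequencing was used to map where Atonal lies on the genome in the brains of Drosophila melanogaster L3 larvae, the last larval stage. Atonal is a proneural basic helix-loop-helix transcription factor. The larvae carried a knock-in that fuses Atonal to GFP, and the fusion was precipitated with an antibody against GFP. The 4 libraries fall into 2 immunoprecipitated (IP) libraries and 2 input libraries, for which the labels give 10% of the sonicated volume of 400 brains. The file analysed here is a single list of peaks for the series. How the input libraries entered the calls is not given in the sources used here, so IP and input were not compared library by library. The list has no replicate error, and neither the read depth nor the values of a single library were analysed here.

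The list held 3280 peaks on 12 sequences, which carry the names of release 5 of the fly genome. Of these, 1929 peaks lay on the arms 2L, 2R, 3L, 3R, 4 and X. The other 1351 peaks, 41.2% of the list, lay on the 6 sequences whose names end in Het, which hold heterochromatin assembled apart from the arms. The peaks were narrow, with a median width of 110 bp, quartiles of 86 and 148 bp and a range from 71 to 2933 bp. Together they covered 438.6 kb. No peaks overlapped, and the smallest gap between neighbours was 76 bp. The score that the authors gave each peak had a median of 25, quartiles of 18 and 36 and a range from 13 to 530, and 288 peaks (8.78%) carried the lowest score of 13. Positions are given here counted from 1. No gene, promoter or sequence motif was assigned to a peak, because the genome and annotation of release 5 were not used here. The position of ato itself relative to the peaks was therefore not analysed here.

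The first comparison asked whether the peaks were spread over the sequences in proportion to their length. They were not: the Het sequences held 146.2 peaks per Mb and the arms 16.12 peaks per Mb, a ratio of 9.07. Counting peaks within 10 kb of each other once brought the ratio to 3.83. That setting joins chains of neighbours into 1 group, so it lowers the count of dense sequence most, by construction. With all peaks counted, the 6 Het sequences were each denser than any arm. XHet had 171.5 peaks per Mb (35 peaks), but 22 of these lay in 1 run, and without it the density was 63.7, below the other Het sequences. Next were 3RHet with 158.4 (395 peaks) and 3LHet with 158.1 (403 peaks). 2RHet had 130.5 peaks per Mb (428 peaks), 2LHet 130.1 (48 peaks) and YHet, which belongs to the Y chromosome, 121.2 (42 peaks). Among the arms, chromosome 4, the small and largely heterochromatic chromosome of the fly, was the densest with 44.65 peaks per Mb (60 peaks). The long arms lay lower, at 20.19 peaks per Mb on 3L (495 peaks), 19.17 on 2R (396 peaks), 16.97 on 2L (390 peaks), 12.05 on 3R (335 peaks) and 11.29 on X (253 peaks). An exact permutation test over the 12 sequences, two-sided, gave p = 0.0022 for the difference in mean density, which is the smallest p that 6 against 6 sequences allow. A bootstrap over windows of 100 kb gave a ratio of 9.12 with a 95% interval from 7.77 to 10.7. The Het sequences made up 7.17% of the length spanned by peaks. Length was taken as the end of the last peak on each sequence, so every density is an upper bound.

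**Figure D1:**
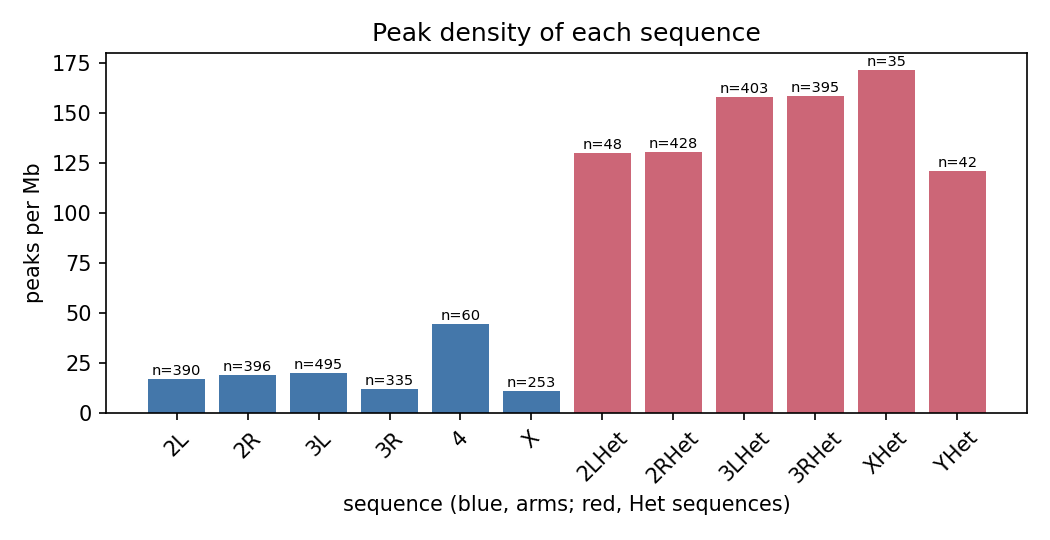
Peaks per Mb (vertical axis) on each of the 12 sequences (horizontal axis), with the number of peaks above each bar; arms are blue and Het sequences red. The Het sequences lie between 121.2 and 171.5 peaks per Mb, and the densest arm, chromosome 4, reaches 44.65.

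Tested one by one with an exact binomial test against the share of the spanned length, each sequence departed from its share after Benjamini-Hochberg adjustment over the 12. The 6 Het sequences and chromosome 4 were above it, and the 5 long arms were below it. The share was of the length of all 12 sequences, so the dense Het sequences lower the values of the arms. Beside the 16.12 peaks per Mb of the arms together, 2L (16.97), 2R (19.17) and 3L (20.19) lay higher. 3R (12.05) and X (11.29) lay lower, and the planned test against the arms alone is not given here. 3RHet carried 6.23 times its share (exact binomial test, adjusted p = 5.14e-179), and 2RHet 5.13 times (adjusted p = 2.42e-164). Chromosome 4 carried 1.75 times its share, with 60 peaks against 34.2 expected (exact binomial test, adjusted p = 4.73e-05). X carried 0.444 times its share, with 253 peaks against 570 (exact binomial test, adjusted p = 1.22e-57), and 3R 0.474 times (adjusted p = 1.71e-65). These p-values treat peaks as independent and are too small where peaks lie in clusters. The excess on chromosome 4 did not hold under a stricter score (20 peaks above 25 against 16.3 expected, exact binomial test, adjusted p = 0.32), and without the 100 kb at each end, which held most of its peaks, its direction turned (18 peaks against 27.2, adjusted p = 0.09). When peaks within 10 kb of each other were counted once, 2LHet, 2RHet, 3LHet, 3RHet and YHet stayed above their share and X stayed below it, and the other 6 sequences did not pass (chromosome 4 at 1.01, XHet at 1.02, 2R and 3L at 1.02, 3R at 0.894 and 2L at 0.872 times their share). XHet also did not pass among scores above 25, with 5 peaks against 2.47 (exact binomial test, adjusted p = 0.11).

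Within the long arm sequences, the density was higher in the 2 Mb at the centromere end on 2L, 2R, 3L and X and not on 3R. The Het sequences were not part of this comparison, and 3RHet held 158.4 peaks per Mb. The result on 3R is therefore one of its arm sequence alone. How far each arm sequence reaches towards the centromere was not examined, so the arms may be compared over unlike stretches. On 3L the 2 Mb nearest the centromere held 230 of 495 peaks, or 115 peaks per Mb against 11.8 on the rest of the arm, a ratio of 9.77 (exact binomial test, adjusted p = 4.5e-113). On 2L the same part held 82 peaks per Mb against 10.8, a ratio of 7.61 (exact binomial test, adjusted p = 3e-69). On X it held 54 peaks per Mb against 7.11, a ratio of 7.6 (exact binomial test, adjusted p = 4.3e-46). On 2R it held 74.5 peaks per Mb against 13.2, a ratio of 5.63 (exact binomial test, adjusted p = 6.4e-50). On 3R it held 23 of 335 peaks, or 11.5 peaks per Mb against 12.1 (ratio 0.951, exact binomial test, adjusted p = 0.92). The size of the ratio depended on the length taken. On X it was 14.7 over 1 Mb and 3.9 over 4 Mb, and over 4 Mb it was 4.7 on 2L and 5.72 on 3L. With peaks within 10 kb counted once, which lowers dense sequence most by construction, the ratio over 2 Mb was 2.78 on X, 2.85 on 2L, 3.01 on 2R and 3.05 on 3L. The share of peaks in this part was 6.87% on 3R and 42.4% on the other 4 long arms together, a difference that passed Fisher's exact test (two-sided p = 1.3e-41). Since 3R was set apart because of these same counts, this p restates the difference and adds no support. The result on 3R depended on where the part ended, since over 4 Mb in place of 2 Mb its density was 20.2 peaks per Mb against 10.7 (ratio 1.9, exact binomial test, adjusted p = 2.4e-06), with 29 peaks in each of the bins from 2 to 3 Mb and from 3 to 4 Mb. This comparison was chosen after the positions had been seen, and its p-values too treat peaks as independent.

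**Figure D2:**
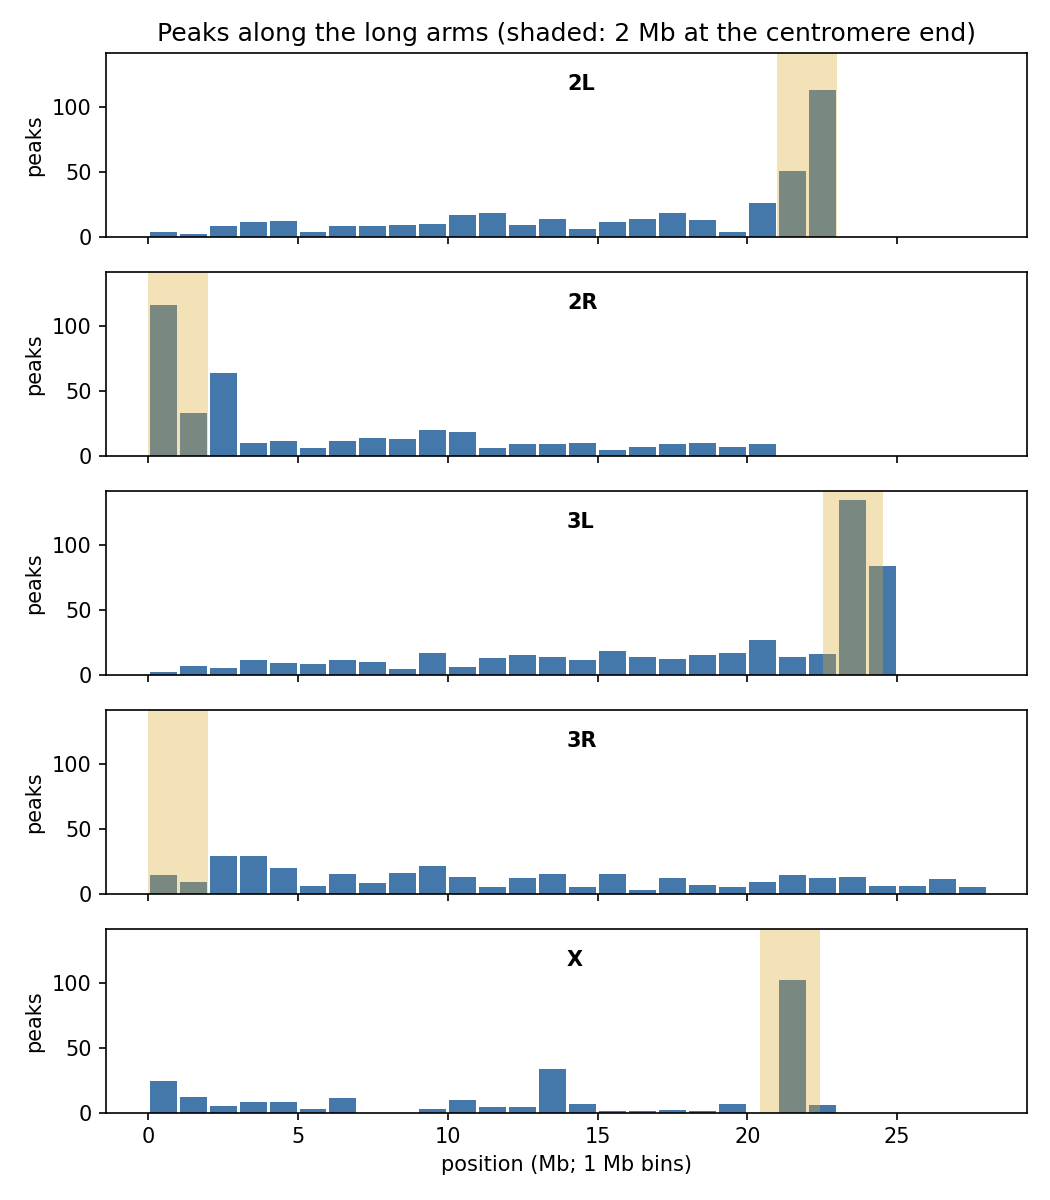
Number of peaks per 1 Mb bin (vertical axis) against position in Mb (horizontal axis) along 2L, 2R, 3L, 3R and X; the shaded part is the 2 Mb nearest the centromere. The last bins of 2L and 3L, the first bin of 2R and the bin from 21 to 22 Mb of X (102 peaks) stand above the rest of their arms, and the first 2 bins of 3R hold 14 and 9 peaks.

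Outside the bins at the centromere end, X carried fewer peaks than the long autosomal arms. The 20 bins of 1 Mb on X held 7.25 peaks each on average (SD 8.44) and the 85 bins of 2L, 2R, 3L and 3R 11.8 (SD 7.98), a difference of -4.57 peaks per Mb (permutation test over bins, two-sided, p = 0.025). That p treats neighbouring bins as independent and covers spread between bins, not between chromosomes. The sex of the larvae, and with it the number of X copies, was not analysed here. The lower count can therefore not be read as less Atonal on X. The autosomal bins included that of 2R from 2 to 3 Mb, with 64 peaks, and left out that of 2L from 20 to 21 Mb, with 26 peaks. The medians were 4.5 on X and 11 on the autosomal arms. No peak lay in 2 of the X bins, those from 7 to 9 Mb, and each autosomal bin held at least 1. One bin of X, from 13 to 14 Mb, held 34 peaks, most of them in a single run. Among the peaks with a score above 25 the difference was -1.3 peaks per Mb and did not pass the permutation test (p = 0.18). That list holds 1560 of the 3280 peaks, so a difference per Mb is smaller there by construction. Over the whole of X, the peaks were 0.439 times its share of the 12 sequences at scores above 25 and 0.444 times with all peaks. That share counts the Het sequences, which hold a larger part of the peaks at higher scores and so lower the values of the arms. Against the same share, 2L went from 0.667 to 0.521, 2R from 0.754 to 0.712, 3L from 0.794 to 0.701 and 3R from 0.474 to 0.381. X thus fell less than these arms, and how much of the smaller difference is by construction was not tested.

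Peaks lay close together more often than random placement gave. Of all peaks, 42.2% had another peak within 1 kb, against a mean of 13.9% (range 11.6 to 16.3%) when peaks were placed at random on their own sequence 1000 times. On the arms the share was 34.5% against 3.88%, and on the Het sequences 53.1% against 28.3%. When peaks were moved only within their own window of 100 kb, so that the regional density was kept, random placement gave 15.4% on the arms and 31.7% on the Het sequences. Each observed share was above all random placements, which gives p = 0.001 (permutation, one-sided), the smallest that 1000 placements allow. Random places could fall anywhere on the length, also where reads cannot be aligned and no peak can be called. Part of the excess may come from that, and its size was not examined. The test also cannot tell separate sites from 1 broad region called in pieces. Grouping peaks less than 1 kb apart gave 476 runs of at least 2 peaks, and 11 runs had 10 or more.

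The 3 longest runs lay on the X chromosome sequences. On XHet, 22 peaks lay between positions 190055 and 204053, a stretch of 14.0 kb of which the peaks covered 72.5%. Of those, 17 carried the lowest score of 13, and their median width was 286.5 bp. Of the same 22 peaks, 6 were among the 15 widest of the list, and these lay 77 to 115 bp from their nearest neighbour. Whether this run, or any run below, holds separate sites or a broad region called in pieces was not tested. The number of peaks in a run is therefore a number of calls and need not be a number of sites. On X, 21 peaks lay between 13940009 and 13951032, with a median score of 15 and a cover of 27.3%. Near the centromere end of X, 15 peaks lay between 21799502 and 21805682 with a median score of 31. On 3L, 14 peaks lay between 23105691 and 23110948 with a median score of 13, and a further 14 between 23508546 and 23514520 with a median score of 17. On 2L, 13 peaks lay between 22410255 and 22415798, and 10 of these had the lowest score. On 2R, 12 peaks lay between 751079 and 756306, 11 of them at the lowest score, and on X a further 12 lay between 21770960 and 21775568 with a median score of 20.5. The window of 100 kb with most peaks was on 2RHet, from 2200001 to 2300000, with 35 peaks of median score 23.

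The next comparison asked whether score went with the kind of sequence. Peaks on the Het sequences scored higher, with a mean of 33.2 (SD 19.8, n = 1351 peaks) against 28.8 (SD 24.5, n = 1929 peaks) on the arms and medians of 28 and 23. The difference of 4.47 passed a permutation test over peaks (two-sided, p = 1e-05, the smallest that the resamples allow, and 7e-05 adjusted over 7 score comparisons). Peaks are not replicate samples, and this p describes the list alone. The Het share was higher among peaks with scores of 26 or more than below. It was 34.5% (95% Wilson interval 31.6 to 37.6%) among the 959 peaks with scores of 13 to 18, 33.9% (30.6 to 37.3%) at 19 to 25, 43.1% (39.7 to 46.7%) at 26 to 36, and 54.2% (50.8 to 57.7%) among the 802 peaks at 37 or more. The odds ratio between the highest and the lowest of these 4 score classes was 2.25 (Fisher's exact test, two-sided, p = 8.7e-17).

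Taken chromosome by chromosome, 4 of the 5 Het sequences with a matching arm scored above it. The mean difference was 9.74 for 2LHet over 2L (permutation test, adjusted p = 0.0017), 5.16 for 3RHet over 3R (adjusted p = 0.018), 3.7 for 3LHet over 3L (adjusted p = 0.021) and 3.01 for 2RHet over 2R (adjusted p = 0.025). XHet went the other way, with a mean of 21 against 31.8 on X, a difference of -10.9 (permutation test, adjusted p = 0.025) and medians of 13 and 23. Without the run between 190055 and 204053, the 13 remaining XHet peaks had a mean of 32.1 and the difference was 0.227 (p = 0.98, permutation). YHet, which has no matching arm, had a median score of 37.5. Chromosome 4 had a median score of 18, and 28.3% of its peaks carried the lowest score. Within the 5 long arms, the 674 peaks in the 2 Mb nearest the centromere had a mean score of 30.4 and the other 1195 peaks 28.1, a difference that did not pass the permutation test (adjusted p = 0.053).

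Most of the 15 highest scores lay on the arms and outside the 2 Mb nearest the centromere. The positions of the tagged ato locus and of any marker sequence carried by the knock-in were not analysed here, so it is open whether any peak listed next, among them the wide ones on X, 3L and 3R, marks the engineered sequence. Of the 15 peaks with the highest scores, 12 lay on arms and 3 on Het sequences, and 2 of the 15 lay in the 2 Mb at the centromere end of a long arm. Of all 3280 peaks, 1929 lay on arms and 674 in these parts of the long arms. At scores of 37 or more the Het share was 54.2%, so the arms did not hold most peaks at that wider cut. The highest score, 530, belonged to a peak of 154 bp on 3R (18309429 to 18309582), and the nearest other peak was 133486 bp away. The second, 483, belonged to a peak of 1188 bp on 3L (17352898 to 17354085). The third, 241, belonged to the widest peak of the list, 2933 bp on X (2684321 to 2687253). A peak of score 137 and 534 bp followed on X at 2690144 to 2690677, after a gap of 2890 bp. On 3R, peaks of score 211 (8293394 to 8293468), 201 (3521463 to 3521542) and 153 (4102323 to 4104059) followed, the last of them 1737 bp wide. The centromere end of X held a peak of score 197 (21397797 to 21397980). On 3L, a pair of peaks with scores of 160 and 168 lay at 20469983 to 20470314 and 20477119 to 20477423. On 2R, peaks of score 164 (10785219 to 10785291) and 147 (621048 to 621128) were 73 and 81 bp wide. The Het peaks among the 15 were on 3RHet (2136637 to 2136717, score 191) and 3LHet (446690 to 446760, score 144, and 2501020 to 2501184, score 137).

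Across all peaks and on the arms, the sign of the relation between score and width depended on the measure. Across all 3280 peaks Spearman's rho was -0.0645 (permutation, adjusted p = 0.00042), and Pearson's r was 0.158 (adjusted p = 0.00064). On the Het sequences both were negative, with rho = -0.118 (adjusted p = 0.00012) and r = -0.117 (adjusted p = 0.00071). On the arms rho was -0.0392 (adjusted p = 0.087) and r was 0.29 (adjusted p = 0.00012). Without the 2 peaks of each set whose scores lie farthest from the median of that set, r was 0.114 over all peaks, 0.261 on the arms and -0.115 on the Het sequences. These are correlations across peaks, which are not independent replicates, and 3 sets of peaks were tested. Of the 15 widest peaks, 8 carried the lowest score of 13, and 6 lay on XHet. Of the 15 widest, 3 were also among the 15 with the highest scores.

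**Figure D3:**
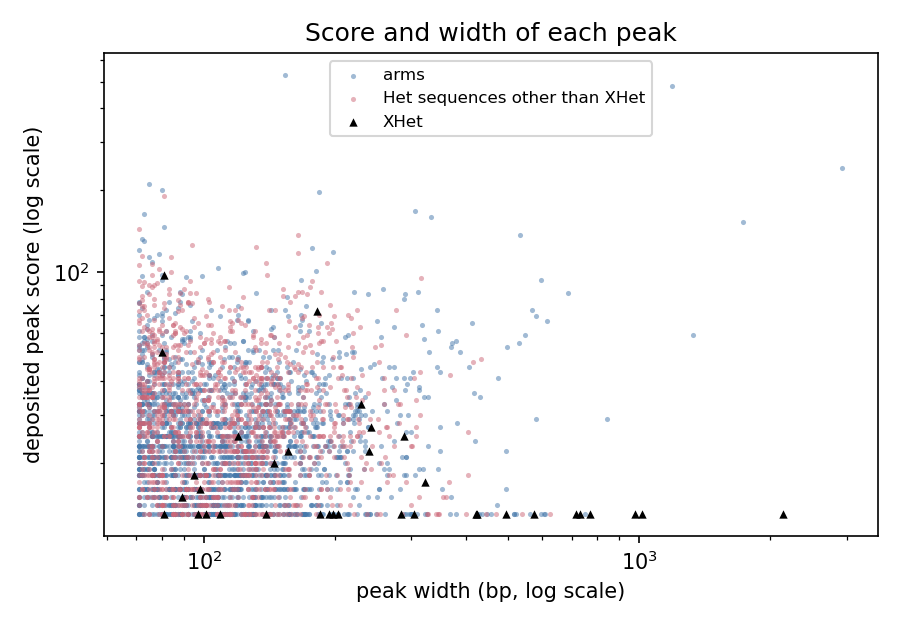
Deposited peak score (vertical axis, log scale) against peak width in bp (horizontal axis, log scale), 1 point per peak; arms are blue, XHet is shown as black triangles and the other Het sequences are red. The wide peaks include arm peaks with high scores, such as the 2933 bp peak of score 241 on X, and peaks at the lowest score of 13, such as the 2142 bp peak on XHet.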

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

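No paired analysis was possible because the deposited list has no values for single libraries, and for the same reason no replicate could be left out. The alternatives set in advance for promoters, introns, motifs, gene lists and non-coding genes were not run, since they need the release 5 genome and annotation. For the number, width and density per sequence of the peaks, a stricter score, merging of touching peaks and removal of 100 kb at each sequence end were fixed before the data were examined. The comparison of Het with arm sequences, to which they were also applied, was itself not in the plan. All other alternatives, including the stricter score for positions along arms, clustering and X against autosomes, were chosen after seeing the data. Of 85 alternative values for 18 results, 77 kept the direction and the side of the threshold (for counts, stayed within 1.5 times). Some of these could not have changed or add little. No peaks touched, the smallest gap being 76 bp, so merging altered nothing. Leaving out a sequence above its share takes it out of the number of such sequences by construction, and many of the values are repeats with 1 sequence left out. The ratio of Het to arm density stayed past the threshold in each, from 8.43 to 9.7 with any 1 of the 12 sequences left out (largest p = 0.0043, exact permutation), and was 12.4 at scores above 25, 9.61 without sequence ends and 3.83 with peaks within 10 kb counted once. That last setting counts dense sequence as few groups by construction, and it also brought the centromere-end ratio to 2.85 on 2L, 3.01 on 2R, 3.05 on 3L and 2.78 on X. The number of sequences above their share was 7, and 5 in each of those 3 settings, in which chromosome 4 and XHet lost their calls. Removal of the ends left almost none of XHet, and turned chromosome 4 to 0.662 times its share. The list of scores above 25 held 1560 peaks, by construction. On 3R the ratio at the centromere end went from 0.951 to 1.17 with 1 Mb and 1.9 with 4 Mb, where the bins from 2 to 4 Mb enter. The density of XHet went from 171.5 to 63.7 peaks per Mb without its longest run. The XHet minus X score went from -10.9 to 0.227 without the longest run. X minus autosomes went from -4.57 to -1.3 peaks per Mb at scores above 25, where fewer peaks make a difference per Mb smaller by construction. Construction may not be all of it, since X fell less against its share of the 12 sequences than the long autosomal arms did. Without runs of 10 or more peaks, X minus autosomes was -5.62, and the cause was not tested. Score and width changed sign between Spearman and Pearson, to 0.158 over all peaks and 0.29 on arms; the cause was not tested. Depth is unknown, so it cannot be said what weaker binding the list leaves out.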

Other observations

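The tests of explanations in this part were chosen after the positions and scores had been seen, and among them only that of identical repeat copies was set out before the values it measures were known. Of the settings given for chromosome 4, the stricter score and the removal of sequence ends were fixed beforehand, and counting peaks within 10 kb once was not. Chromosome 4 and YHet were both denser than the long arms with all peaks counted, but for chromosome 4 this depended on the setting. At scores above 25 it held 1.23 times its share, above the 5 long arms (0.381 to 0.712). Without 100 kb at each end it held 0.662 times its share, below 2L (0.704), 2R (0.79) and 3L (0.81) and above 3R (0.503) and X (0.453). With peaks within 10 kb counted once it held 1.01 times, beside 1.02 on 2R and 3L and above 2L (0.872), 3R (0.894) and X (0.326). Chromosome 4 had a median score of 18, with 17 of 60 peaks at the lowest score, and YHet a median of 37.5, with 3 of 42. The difference in score between them was not tested.

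The setting that counts peaks within 10 kb once joins dense sequence into few groups by construction. The higher density of peaks on Het sequences, 9.07-fold with all peaks and 3.83-fold with that setting, is the pattern that most needs a second look, because heterochromatin is rich in repeats. Weak calls near the threshold do not account for it as a whole, since at scores of 37 or more the ratio of Het to arm density was 15.4 (exact permutation p = 0.0022). That ratio restates the Het share of 54.2% at these scores, which was already known. Its p is the smallest that 6 against 6 sequences allow. A few dense runs do not account for it either, since the median window of 100 kb held 14 peaks on Het sequences (bootstrap 95% interval 12 to 15) and 1 on arms. Reads from repeat copies placed at several loci may contribute and stay open. If copies were called alike, Het peaks would share both width and score more often than chance, and 228 pairs did, against a mean of 214 (95% range 185 to 245) with scores permuted over widths (p = 0.18, 10000 permutations), which decides nothing because randomly placed reads also blur identical copies. Binding of Atonal or an off-target effect of the antibody in heterochromatin was not tested, as no IP from animals without GFP was analysed here.

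The wide peaks on arms with high scores are loci to look at in the reads. They are the peaks of 2933 bp on X at 2684321 and 1188 bp on 3L at 17352898, with scores of 241 and 483, and the peak of 1737 bp on 3R at 4102323 with a score of 153. They were named after their values had been seen. Whether any of them lies at the tagged ato locus or at marker sequence of the knock-in construct was not tested, and until it is, their scores and widths cannot be read as Atonal binding.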
